A study of Mus musculus with 9 samples.

How the data were processed

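Gene expression was measured by RNA sequencing in the locus coeruleus, the main noradrenergic nucleus of the brainstem, of mice at postnatal day 35. Per the labels' protocols, unfixed frozen brains were cut into 8 µm sections, stained with crystal violet and dissected with a UV laser. The series' design text gives 100 cells per mouse. Libraries were made with a SMARTer Ultra Low Input RNA kit, which amplifies full-length cDNA from very small amounts of RNA. The cells were therefore chosen on stained sections, and no marker gene used to choose them is named in the sources used here. Each of the 9 libraries came from 1 mouse, 4 wild type (WT) and 5 conditional knockout (cKO, labelled ASL-LC cKO), so that the mouse was the replicate.

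The authors deposited a table of raw read counts per gene symbol and a table of normalized values. Per the submitters' processing notes, bcl2fastq 2.17.1.14, cutadapt, TopHat2 2.0.10, HTSeq 0.6.1p1 and DESeq2 1.6.3 were used with the mouse genome build mm10. The gene annotation, the strand setting of the counting and the Cre driver are not given in the sources used here. The signal values in the authors' normalized table were the deposited counts divided by 1 size factor per library. These factors equalled DESeq2 median-of-ratios factors computed from the counts, with a largest absolute difference of 5.77e-15. The count table held 24421 genes, of which 7171 had no count in any library. It held 0 mitochondrially encoded genes, so the mitochondrial share planned as a library property could not be computed. Amplified reads without molecular identifiers are not independent molecules, so that intervals and floors cover counting error only.

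Genes were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, using TMM normalization, the filterByExpr function by group and the quasi-likelihood F test with genotype as the only term. The filter kept 12423 genes. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Levels are given as CPM, counts scaled to the TMM-adjusted library total, as mean ± SD over mice. The standard error (SE) of a log2 fold change was computed as its size divided by the square root of F, and fold changes carry edgeR's prior count of 0.125. Single values were compared with two-sided exact permutation tests of log2(CPM + 1) over all 126 splits of the 9 libraries into 4 and 5, which can give no p-value below 0.00794. Where a group held no counts of a gene, the fold was set against a floor of 3 counts over the group. With 1 to 9 counts a ratio of group sums is given with an exact 95% interval. Gene positions are from GENCODE M21 (GRCm38, the assembly of mm10), in which 23376 symbols of the table (95.7%) had a match. This annotation need not be the one used by the authors. In it Nos1, Ddc, Slc18a2, Gch1 and Snca also overlap antisense, pseudogene or unclassified transcripts, which makes their counts uncertain where such reads were not told apart.

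Gene lists were fixed before the data were examined and covered 22 biological groups and 14 sets of markers. These included noradrenergic identity, arginine and nitric oxide, energy metabolism, stress responses, neuronal function and other cell types. A further fixed list, of mitochondrially encoded genes, dropped out because the table held 0 of them. Of 765 list entries, those of the dropped list included, 749 were found in the table. The 5 tested genes required for a list test were reached by 28 lists. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Adjusted p-values within a list are called adjusted over the list alone. Such values are not corrected for the number of lists. Marker sets were also compared as the mean of log2(CPM + 1) per library, with exact permutation tests adjusted over 14 sets. The named genes were also set by a rule fixed before the data were examined. They comprised Asl and 10 anchor genes, up to 12 genes past the threshold in each direction, and up to 4 members of each biological list (2 of each marker set) with the smallest p. Where fewer than 5 genes passed in a direction, those with the smallest p up to 5 were named as not passing, leaving out numbered gene models and pseudogenes. From the genes allowed by this rule, those described carry their values.

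The procedure was tested on simulated counts for the 12423 genes in the comparison of cKO with WT, with 200 genes drawn to be changed. It recovered 12 of 46 changes of 2-fold (26.1%) and 30 of 48 of 4-fold (62.5%). For 8-fold it recovered 42 of 48 (87.5%) and for 16-fold 45 of 45 (100%), with 7 false calls among 136. Planted genes that the filter removed from the simulated counts are not in these totals, so recovery of all planted changes was lower. These rates hold only with 200 changed genes, since the Benjamini-Hochberg cut-off loosens as more genes pass. With few changed genes recovery is lower. In the real data Ccdc17, with a log2 fold change of 3.01 and an unadjusted edgeR p of 0.000776, was not called. A shift of 0.5 log2 units was planted in 1 list, the cytosolic ribosomal proteins, which was found, and 0 other lists were called. This is the largest list, with 73 genes tested in the real data. Shorter lists and smaller shifts were not simulated. Genes were drawn independently of one another, so the simulation could not show false list calls that arise from correlated genes. In the real data the estimated correlation of the ribosomal protein list was 0.316. Total counts ranged from 8958530 to 12177715 per library, and the biological coefficient of variation was 0.546, so that single changes of 2-fold were mostly below what the comparison could detect.

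Pairs of libraries within a group differed far beyond sampling noise, with chi-square values per degree of freedom of 21.8 to 92.2 over 16 pairs, so all 9 libraries were kept as separate replicates. Alternatives chosen before the data were examined were other normalizations and filters, DESeq2 1.42.0, limma-voom, replicate number as a block, covariates for sex-linked expression, oligodendrocyte markers and detected genes, and leaving out each library in turn. Alternatives added after the data were seen left out Rn45s (a ribosomal RNA precursor) from the library size, left out the 3 least correlated libraries (WT 1, cKO 1 and cKO 3), left out the 2 libraries highest in cerebellar markers (WT 3 and cKO 2), or added a term for library size. For this term libraries were divided into 4 with total counts under 10000000 and 5 with more. The division was also used for values within each class.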

Results

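Cells of the locus coeruleus were profiled in 4 WT and 5 cKO mice to find differences in gene expression in a noradrenergic nucleus. The targeted gene, Asl, encodes argininosuccinate lyase, which releases arginine in the urea cycle and in the recycling of citrulline for nitric oxide synthesis. Total counts in WT mice 1 to 4 were 8958530, 9041289, 11356165 and 12177715. In cKO mice 1 to 5 they were 9524730, 10975265, 11134276, 9464246 and 11116645. Between 13226 and 14707 genes were detected per library. Total counts, detected genes, the share of the 50 most counted genes and the share of Rn45s showed no difference between genotypes past the threshold by exact permutation tests (6 properties including detection at 10 counts and at equal depth, lowest adjusted p = 0.937). Noradrenergic genes were abundant in all 9 libraries. Dbh, which encodes dopamine beta-hydroxylase, ranged from 2634 to 4226 CPM, and Slc18a2, which encodes the vesicular monoamine transporter, from 2810 to 4522 CPM.

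Asl fell in every cKO mouse. It was expressed at 70.8 ± 23.3 CPM in WT mice (SD, n = 4; 99.2, 80.1, 48.6 and 55.2 CPM) and at 11.8 ± 3.65 CPM in cKO mice (n = 5; 13.7, 16.8, 10.3, 10.8 and 7.23 CPM), which is 16.6% of the WT level. The log2 fold change was −2.59 (SE 0.32), with an adjusted p of 0.00778 by edgeR's quasi-likelihood test and an exact permutation p of 0.00794, the smallest that 126 splits can give. All 5 cKO libraries lay below all 4 WT libraries. The gene lies at chromosome 5, 130011258 to 130029247, on the minus strand (GRCm38), and no other annotated gene overlaps it. The difference in mean log2(CPM + 1) was −2.78 among the 4 libraries under 10000000 counts (2 WT, 2 cKO) and −2.16 among the 5 larger ones (2 WT, 3 cKO). The call was lost with replicate number as a block (log2 fold change −2.42, adjusted p = 0.113), with Y-linked expression as a covariate (−2.28, adjusted p = 0.451), without WT 2 (−2.52, adjusted p = 0.0573) and without the 3 least correlated libraries (−2.39, adjusted p = 0.471). Which exons were deleted is not given in the sources used here, so reads from exons that remain in the genome are counted as Asl.

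Asl was the only gene past the threshold. Of 12423 genes tested with edgeR, 0 were higher and 1 was lower in cKO mice at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 299 genes, 136 higher and 163 lower, where 621 would be expected by chance. DESeq2 called 10 genes, 4 higher and 6 lower, with 607 at an unadjusted p under 0.05, and left the adjusted p of 9883 genes undefined. The count of 1 became 0 with replicate number as a block, with the Y-linked covariate, without WT 2 and without the 3 least correlated libraries. All cKO libraries lay above all WT libraries for 62 genes and below them for 64, together 1.01% of the genes tested, where chance gives 1.59%.

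Within the noradrenergic group, Th was lower in cKO mice while the other transmitter genes lay close to WT levels. Th encodes tyrosine hydroxylase, the rate-limiting enzyme of catecholamine synthesis, and was measured at 2448 ± 601 CPM in WT mice (n = 4) and 1162 ± 516 CPM in cKO mice (n = 5), or 47.4% of WT. Its log2 fold change was −1.08 (SE 0.27), and 4 of 5 cKO libraries lay below all WT libraries. Th did not pass over all genes tested (edgeR adjusted p = 1.00, unadjusted p = 0.00109). It passed when adjusted over the list alone (p = 0.0228), and the exact permutation p was 0.0317. The call over the list alone was lost in 7 of 26 alternatives: with the Y-linked covariate (edgeR p adjusted over the list alone = 0.759), without WT 1 (0.0897), WT 3 (0.0529), WT 4 (0.101), cKO 1 (0.0853) or cKO 2 (0.0719), and without the 2 libraries highest in cerebellar markers (0.145). Th lies at chromosome 7, 142892752 to 142931128, on the minus strand. Among libraries under 10000000 counts the difference in mean log2(CPM + 1) was −1.51, and among the larger ones −0.95. With Y-linked expression as a covariate the log2 fold change of Th was −0.58. This covariate does not measure sex and overlaps genotype, as the Y-linked level was 0.45 higher in cKO mice.

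The enzymes and transporters that act after Th differed by less than their errors. Ddc, which encodes aromatic amino acid decarboxylase, had a log2 fold change of −0.02 (SE 0.17), Dbh of −0.07 (SE 0.15), and Slc6a2, the noradrenaline transporter gene, of −0.00 (SE 0.16). The fold change of Maoa, which encodes a monoamine-degrading enzyme, was 0.06 (SE 0.14). The sign of Ddc, Dbh, Slc6a2, Slc18a2 and Maoa changed in some of the 26 alternative settings. Slc18a2 was at 3237 ± 485 CPM in WT and 3565 ± 597 CPM in cKO mice. Gch1, which encodes GTP cyclohydrolase, the entry enzyme of tetrahydrobiopterin synthesis and thus of the Th cofactor, was at 150 ± 18.7 CPM in WT and 186 ± 30.2 CPM in cKO mice (log2 fold change 0.31, SE 0.18, not past the threshold). Snca, the alpha-synuclein gene, had a log2 fold change of 0.19 (SE 0.18). Of the 21 tested genes of noradrenergic identity, 10 were higher and 11 lower, 1 passed adjusted over the list alone (Th), and the median log2 fold change was −0.00. The list as a whole did not pass (camera adjusted p = 0.696; 0.903 with an estimated correlation).

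**Figure D1:**
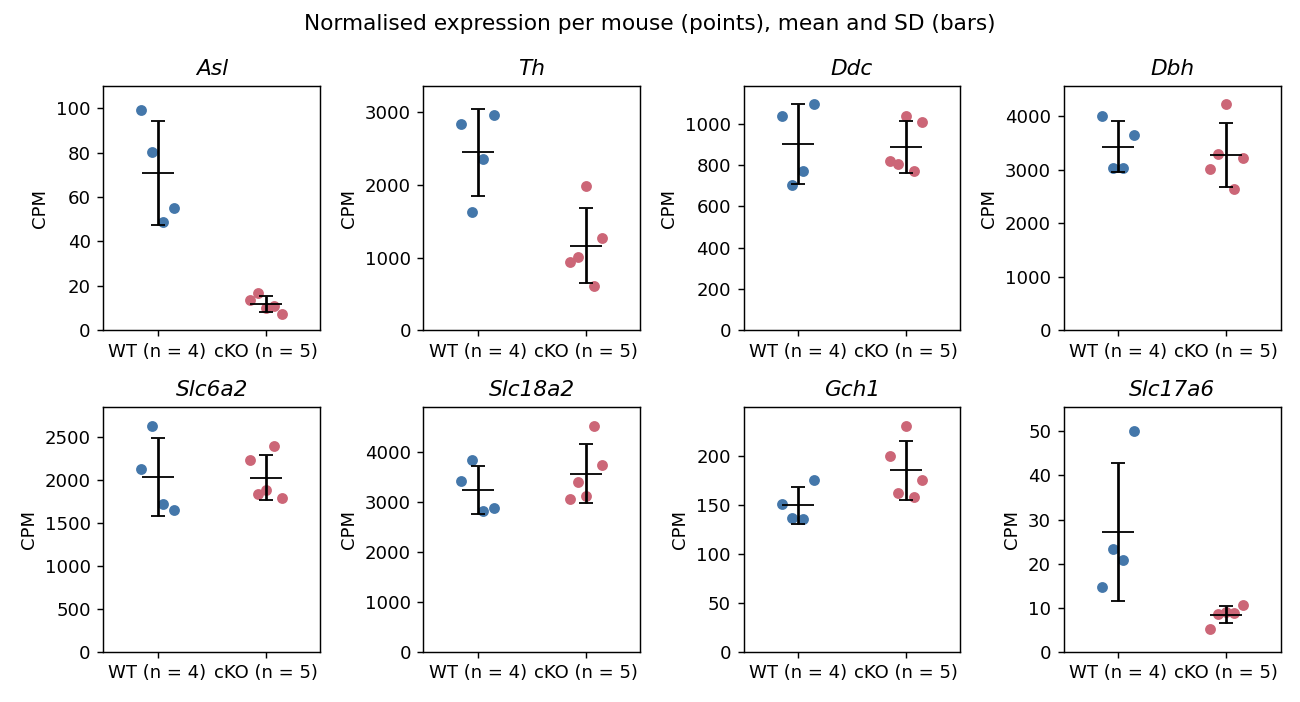
Normalised counts (CPM) of Asl, 6 noradrenergic genes and Slc17a6 in each mouse (points), with the mean and SD of each group (bars); the vertical axes start at 0 and differ between genes. All 5 cKO mice lie below all WT mice for Asl and Slc17a6 and 4 of 5 for Th, while Ddc, Dbh and Slc6a2 overlap.

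Among genes of arginine, urea cycle and nitric oxide metabolism, only Asl passed a threshold, both over all genes tested and over the list alone. Of 22 tested members 12 were higher and 10 lower (median log2 fold change 0.05; mean −0.06). Camera gave an adjusted p of 0.996, and fry, which tests whether members move one way, 0.775. Nos1, which encodes the neuronal nitric oxide synthase, was at 53.4 ± 22.1 CPM in WT and 39.7 ± 11.7 CPM in cKO mice (log2 fold change −0.43, SE 0.31). Ass1, the gene of the enzyme that makes the substrate of Asl, was at 1.07 ± 0.17 CPM in WT and 1.16 ± 0.144 CPM in cKO mice, with 10 to 14 reads in each library (log2 fold change 0.12, SE 0.82). Gatm, which encodes an arginine-using enzyme of creatine synthesis, had a log2 fold change of 0.73 (SE 0.40). Of 11 genes of polyamine metabolism 4 were higher and 7 lower (camera adjusted p = 0.996). Sat1, a spermidine/spermine acetyltransferase gene, was at 142 ± 26.9 CPM and 189 ± 48.9 CPM. The 16 genes of the aspartate-malate shuttle and fumarate (7 higher, 9 lower, adjusted p = 0.898) and the 8 of tetrahydrobiopterin synthesis (6 higher, 2 lower, adjusted p = 0.506) held no gene past the threshold.

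**Figure D2:**
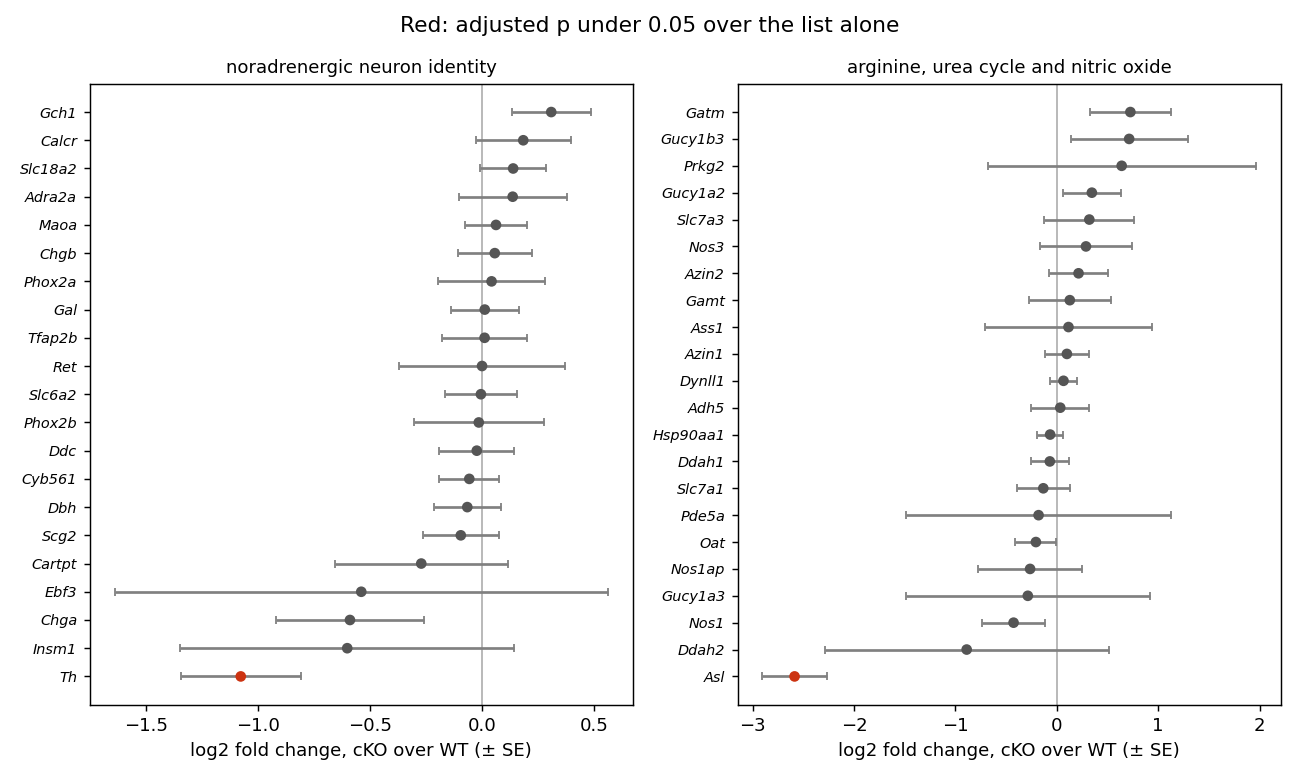
Log2 fold change of cKO over WT with its SE (horizontal axis) for the tested genes of noradrenergic identity (left) and of arginine, urea cycle and nitric oxide metabolism (right). Red marks an adjusted p under 0.05 over the list alone, which Th (−1.08) and Asl (−2.59) reached.

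Beyond Asl, the 4 lower genes with the smallest p did not pass over all genes tested. Slc17a6, which encodes a vesicular glutamate transporter, was at 27.2 ± 15.6 CPM in WT and 8.46 ± 2.01 CPM in cKO mice (log2 fold change −1.69, SE 0.41). All 5 cKO libraries lay below all WT libraries (exact permutation p = 0.00794), and Slc17a6 passed adjusted over the list alone, a list of 4 tested glutamatergic markers (p = 0.0035), but not with the Y-linked covariate (edgeR p adjusted over the list alone = 0.0901) or without WT 4 (0.0653). Its difference in mean log2(CPM + 1) was −1.32 in the libraries under 10000000 counts and −1.69 in the larger ones. Rad18, which encodes a ubiquitin ligase of DNA repair, was at 14.1 ± 10.7 CPM and 1.75 ± 1.12 CPM. Ttr, the transthyretin gene and a marker of choroid plexus, had 211 reads in all WT libraries and 2 in all cKO libraries, a ratio of 131 (95% interval 35.8 to 1089, counting error only). Of the WT reads 147 came from WT 1, and without it the ratio was 51.2 (13.6 to 432). Ttr passed adjusted over the list alone, a list of 3 tested meningeal and ependymal markers (edgeR adjusted p = 0.000415). Over all genes tested its edgeR adjusted p was 0.668. Slc17a6 and Ttr stand here because their p was among the smallest of all genes tested. Their values over the list alone correct neither for this choice nor for the number of lists. Its difference in mean log2(CPM + 1) was −2.89 in the smaller and −1.40 in the larger libraries. Pcsk9, whose product lowers the number of LDL receptors, had 126 reads in WT and 0 in cKO libraries, at least 52.2-fold lower against a floor of 3 counts over the group. Slc17a6 lies at chromosome 7, 51622006 to 51671119, where it overlaps a short unclassified transcript on the same strand and is uncertain to that extent. Rad18 lies at chromosome 6, 112619850 to 112696686, Ttr at chromosome 18, 20665280 to 20674321, and Pcsk9 at chromosome 4, 106442329 to 106464329.

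The 5 higher genes with the smallest p did not pass either. Kcns3, which encodes a modulatory potassium channel subunit, had 2 reads in WT and 260 in cKO libraries, a ratio of 105 (95% interval 28.7 to 869), and was above all WT libraries in 4 of 5 cKO libraries. Def8 was at 14.6 ± 4.18 CPM in WT and 31.6 ± 7.96 CPM in cKO mice, and Mfsd2b, which encodes a sphingosine-1-phosphate exporter, was at 0.445 ± 0.299 CPM and 3.53 ± 0.809 CPM. Ccdc17 was at 1.00 ± 0.63 CPM and 8.15 ± 3.00 CPM, and Chml, which encodes a Rab escort protein, at 11.4 ± 4.90 CPM and 30.4 ± 11.8 CPM. Of these, 4 are uncertain, because Kcns3 overlaps a processed pseudogene on the opposite strand, Ccdc17 overlaps an antisense transcript, Chml overlaps Opn3 on the same strand, and Def8 lies within the span of another annotated protein-coding gene on the same strand. DESeq2 called Kcns3, Ccdc17, Ttr, Pcsk9 and Rad18 in addition to Asl (adjusted p = 0.0121, 0.00313, 0.00313, 0.00313 and 0.0254). Its other calls, Slc19a3 and Phxr4 (0 reads in WT), C8b (0 reads in cKO) and Tac1, were outside the naming rule and are named here after their values were seen. Kcns3 lies at chromosome 12, 11090202 to 11151056, Ccdc17 at chromosome 4, 116596654 to 116600266, Def8 at chromosome 8, 123423527 to 123463270, Mfsd2b at chromosome 12, 4862440 to 4874359, and Chml at chromosome 1, 175682237 to 175692901.

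Of the 28 gene lists tested, 1 passed. Of the 73 genes of cytosolic ribosomal proteins tested, 67 were higher and 6 lower in cKO mice, with a median log2 fold change of 0.13 (camera adjusted p = 0.0053). The list did not pass with an estimated correlation (adjusted p = 0.903) or with fry (adjusted p = 0.775). No member passed alone. The difference in the mean of log2(CPM + 1) over the members was 0.20 in the 4 libraries under 10000000 counts and 0.056 in the 5 larger ones (exact permutation p = 0.233 within the classes). The member with the smallest p, Rps3a1, was at 548 ± 36.6 CPM in WT and 664 ± 127 CPM in cKO mice. Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain. The count of lists was 0 with replicate number as a block, without WT 3, without WT 4, without cKO 4 and without the 2 libraries highest in cerebellar markers. It was 2 without WT 1 (with glutamatergic markers) and without cKO 3 (with immediate early genes), and 3 without the 3 least correlated libraries (with cytoskeleton and microglia markers). With the Y-linked covariate it was also 2, but these were proteasome subunits and mesencephalic trigeminal markers, and the ribosomal list did not pass (camera adjusted p = 0.911, median −0.04).

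Energy metabolism and stress groups held no gene past the threshold. Of 68 nuclear-encoded oxidative phosphorylation genes 48 were higher and 20 lower (camera adjusted p = 0.506, median log2 fold change 0.03). Of 25 genes of glycolysis and lactate 10 were higher and 15 lower (adjusted p = 0.372), among them Pdk2, a pyruvate dehydrogenase kinase gene, at 71.7 ± 31.9 CPM in WT and 35.0 ± 11.1 CPM in cKO mice (exact permutation p = 0.0238), and Pfkl, a phosphofructokinase gene, at 37.0 ± 5.75 CPM and 22.2 ± 7.76 CPM. Counts of higher and lower genes were 9 and 13 for the unfolded protein response (adjusted p = 0.996; mean 0.04, median −0.03), 7 and 8 for cytosolic heat shock (0.506), and 16 and 12 for oxidative stress (0.696). They were 15 and 16 for proteasome subunits (camera adjusted p = 0.904, or 0.0144 and higher with the Y-linked covariate). That call rests on the preset correlation of 0.01, whereas 0.53 was estimated for this list in the main setting. Higher and lower genes numbered 14 and 19 for autophagy and lysosome (0.938) and 9 and 6 for apoptosis and p53 targets (0.696). For the interferon response they numbered 8 and 4 (0.898, with a camera direction opposite to the median of 0.14). Hspb1, a small heat shock protein gene, was at 11.8 ± 9.03 CPM and 3.93 ± 2.79 CPM, and Grn, the progranulin gene, at 29.0 ± 8.64 CPM and 17.7 ± 3.93 CPM.

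Neuronal groups likewise held no gene past the threshold. Higher and lower genes numbered 11 and 19 for synaptic vesicles and release (camera adjusted p = 0.696), 19 and 19 for ion channels (0.506), 18 and 13 for transmitter receptors (0.506), 8 and 20 for cytoskeleton and axonal transport (0.330) and 10 and 4 for immediate early genes (0.233). Camera called the cytoskeleton list lower without the 3 least correlated libraries (adjusted p = 0.0496) and immediate early genes higher without cKO 3 (0.0291). Gria4, an AMPA receptor subunit gene, was at 99.6 ± 23.5 CPM in WT and 134 ± 10.7 CPM in cKO mice, with all 5 cKO libraries above all WT libraries (exact permutation p = 0.00794, the smallest possible, before adjustment). Of 20 Parkinson disease genes 7 were higher and 13 lower (adjusted p = 0.696), and of 9 genes of monoamine degradation 4 were higher and 5 lower (0.871; median −0.11).

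Markers of other cell types were compared as 14 sets, of which 0 passed by adjusted exact permutation test and 1 had an unadjusted p under 0.05. A single set could not pass this test, since 1 fully separated set reaches an adjusted p of 0.111 at best and at least 3 such sets are needed to pass, so a difference in 1 or 2 sets could not have been called. The differences in mean log2(CPM + 1), cKO minus WT, were 0.25 for oligodendrocytes, −0.29 for their precursors, 0.21 for astrocytes, 0.22 for microglia, 0.08 for endothelial and mural cells, −0.26 for meningeal and ependymal cells and −0.05 for blood cells. For neurons they were −0.38 for glutamatergic, 0.12 for GABAergic and glycinergic, −0.42 for serotonergic and cholinergic, −0.48 for mesencephalic trigeminal and −0.02 for cerebellar markers. The 6 sets of at least 5 tested genes among these did not pass camera (lowest adjusted p = 0.247, endothelial and mural). In alternative settings camera called microglia markers higher without the 3 least correlated libraries (adjusted p = 0.0195), mesencephalic trigeminal markers lower with the Y-linked covariate (0.0144) and glutamatergic markers lower without WT 1 (0.042). Y-linked genes, expressed in all 9 libraries, were 0.45 higher in cKO mice (exact permutation p = 0.0238, adjusted p = 0.333), and the female-expressed X genes Xist and Tsix differed by 0.28 (exact permutation p = 1). Ly6c1, an endothelial gene, had a log2 fold change of 0.90 (SE 0.40), and C1qb, a microglial complement gene, at 0.145 ± 0.137 CPM and 2.28 ± 1.39 CPM, without passing the threshold. Tph2, the serotonin-synthesis enzyme gene, was at 3.80 ± 3.27 CPM and 0.408 ± 0.542 CPM, and Avil, a sensory neuron gene, at 4.62 ± 3.81 CPM and 0.367 ± 0.666 CPM, also without passing.

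**Figure D3:**
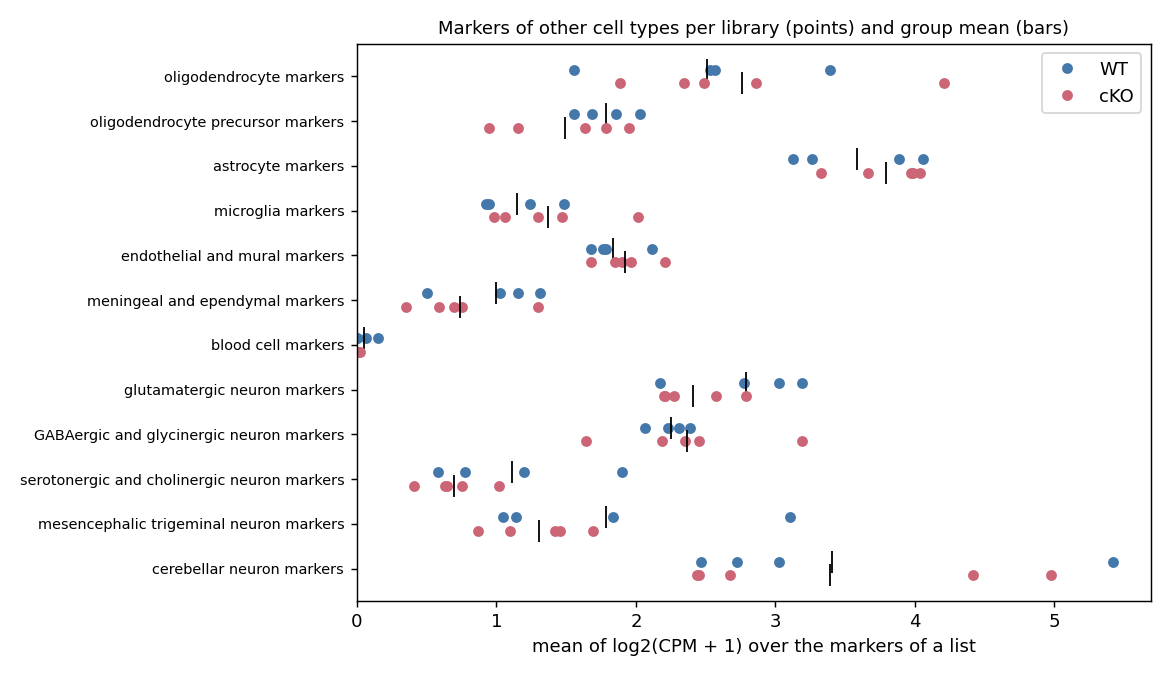
Mean of log2(CPM + 1) over 12 sets of markers of other cell types (horizontal axis) in each library (points) and group means (bars). The 2 groups overlap in every set, and cerebellar markers stand highest in WT 3 (5.42), cKO 2 (4.97) and cKO 4 (4.42).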

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

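Of 166 groups of values examined, 9 held a sample far from the rest of its group by Dixon's criterion, where chance alone gives about 8.3. All values here are on the log2(CPM + 1) scale. Kcns3 stood at 0.284 in WT 2, against 0 in the other WT libraries, and Ttr at 0.244 in cKO 2, against 0 in the other cKO libraries. Both rest on 2 reads. Psma6, a proteasome subunit gene, was at 8.63 in cKO 1, below a range of 9.06 to 9.22 in the other cKO libraries. Fos, an immediate early gene, was at 0.965 in cKO 3, below 3.46 to 4.37. Irf9, an interferon response gene, was at 0.976 in WT 1, below 3.70 to 3.97. C1qb was at 0 in cKO 1, below 1.72 to 2.19. Avil was at 1.34 in cKO 5, above 0 to 0.38. The mean of the blood cell markers was 0.0195 in cKO 1, against 0 in the other cKO libraries. The mean of Xist and Tsix was 1.64 in cKO 5, with 33 and 16 reads, against 0 in the other cKO libraries.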

How the results depend on the processing

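Direction was read only where a log2 fold change exceeded its SE or a call existed. The settings that left out several libraries or Rn45s, or added library size, were chosen after the data were seen. Asl stayed lower in all 26 alternatives (log2 fold change −2.89 to −2.28; adjusted p 4.52e-12 to 0.471) and passed in 22. It did not pass with the replicate block (−2.42), with the Y-linked covariate (−2.28), or without the 3 least correlated libraries (−2.39). The Y-linked covariate does not separate the sexes, because Y-linked genes were expressed in all 9 libraries. Their mean log2(CPM + 1) was 4.88 to 5.58 in WT and 5.51 to 5.95 in cKO mice. The covariate thus overlaps genotype, and a loss under it cannot be read as an effect of sex. The Y-linked gene Ddx3y was at 147 to 270 CPM in the 9 libraries. Xist had at most 2 reads in any library except cKO 5, which had 33. These values argue against a mix of males and females among the libraries. When each library was left out in turn, Asl ranged from −2.75 to −2.38 and was lost without WT 2 (−2.52). The number of genes called was 10 with DESeq2 and 0 with the replicate block, the Y-linked covariate and without the 3 least correlated libraries. It was 0 to 1 when each library was left out. Th was lower in all 26 alternatives (−1.36 to −0.58) and Slc17a6 likewise (−1.89 to −1.21), with neither past the threshold over all genes tested. The number of gene lists past the threshold was 0 with the replicate block, the estimated correlation and fry. It was also 0 without the 2 libraries highest in cerebellar markers. It was 2 with the Y-linked covariate, 0 to 2 when each library was left out, and 3 without the 3 least correlated libraries.

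Some directions turned. With the replicate block, Isl1 was 0.43. With the Y-linked covariate, the log2 fold change was 0.077 for Qdpr, 0.18 for Cyc1, −0.073 for Rps27a and −0.0032 for Rps5. The log2 fold change was 0.38 for Sncg, −0.015 for Kif5b and 0.11 for Tubb3. The median was 0.20 for the list proteasome subunits and −0.041 for the list cytosolic ribosomal proteins. Without the 3 least correlated libraries Sncg was 0.058. The causes were not tested, beyond the fewer samples of the reduced sets. Mice with the same replicate number did not pair: correlations of their deviations were 0.08, −0.08, −0.02 and −0.05, and only WT 1 correlated best with its own number. Leaving mitochondrial and haemoglobin genes out of the library size changed nothing, as the table held 0 mitochondrial genes. The library property planned for the mitochondrial share was not run. Changes up to 8-fold in genes of low counts were recovered less often in the simulation. Below a log2 CPM of 4 it recovered 0 of 19 changes of 2-fold, 5 of 19 of 4-fold, 5 of 11 of 8-fold and 9 of 9 of 16-fold. Planted genes that the filter removed from the simulated counts are left out of these totals. Depth was not varied, and the rates hold for 200 planted changes.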

Other observations

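The tests of the loss of noradrenergic neurons and of library composition for Th were chosen after its values had been seen, as were the library-size classes and the median of the 5 genes below Slc17a6. The tests of the 8 neighbouring genes, of other splits and of depth, transcript length and GC content between the classes were set before their results.

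Gal, the galanin gene, was at 2913 ± 606 CPM in WT and 2939 ± 342 CPM in cKO mice. Hcrtr1, an orexin receptor gene, was at 228 ± 39.3 and 186 ± 57.7 CPM, and Adra2a, an inhibitory adrenergic receptor gene, at 88.7 ± 32.4 and 97.6 ± 12.9 CPM. Of the other genes of the urea cycle and nitric oxide synthesis, Arg1 and Arg2 averaged at most 0.889 CPM in either group and Nos2, Otc and Cps1 had no reads in any library. The arginine transporter gene Slc7a1 was at 80.2 ± 31.6 and 73.1 ± 12.1 CPM, and Ddah1, which encodes an enzyme that degrades methylated arginine, at 252 ± 68.2 and 240 ± 28.4 CPM. These genes did not pass the edgeR threshold where they were tested.

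The lower Th level was weighed against a smaller share of noradrenergic neurons and against library depth or composition. The median log2 fold change of Ddc, Dbh, Slc6a2, Slc18a2, Maoa, Phox2a and Phox2b was −0.0045 (SD 0.068), far from the −1.08 of Th, which argues against fewer noradrenergic neurons. The log2 ratio of Th to Dbh within a library lay between −0.89 and −0.30 in WT and between −2.11 and −1.09 in cKO mice. The difference was −1.07 (exact permutation p = 0.0159). It was −1.20 in the libraries under 10000000 counts and −1.05 in the larger ones. Within the classes the exact permutation p was 0.0167, the smallest that 60 arrangements allow. Depth and library scaling cancel in this ratio, so they do not account for the lower Th. The ratio follows from Th and Dbh values already seen, so its p adds no new evidence. A comparison with 1 reference gene cannot exclude a shift in the cells captured. Of 100 splits of the 9 libraries, the real one included, 4 gave Th an edgeR p as small, so chance stays open. An effect of the loss of Asl on the Th transcript stays open and was not tested, as does an effect of the Cre driver, whose presence in the WT mice is not given in the sources used here.

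Slc17a6, which neurons next to the nucleus use for glutamate release, may have come from neighbouring excitatory neurons captured more often in WT mice. Other genes of such neurons had a median log2 fold change of −0.176 (bootstrap SE 0.514, 8 genes), above the −0.5 that was to argue against this. That bound was wrong, since 3 of the 8, Calca, Adcyap1 and Pdyn, lie above Slc17a6 in WT mice and would hide a small share. The other 5 had a median of −1.02 (SE 1.12). Of these, Cck was at 0.26 (SE 1.47), Nfib at −0.39 (SE 0.56), Foxp2 at −1.02 (SE 1.53) and Penk at −1.37 (SE 1.13). Tac1 had 372 reads in WT and 9 in cKO libraries (ratio 51.4, 95% interval 26.8 to 113). The ratio was 20.3 (10.3 to 45.6) without WT 3, which held 265 of these reads, and at least 121.7 without cKO 2, which held all 9 cKO reads. Among WT libraries Tac1 was lowest in WT 4 (1.02 CPM), where Slc17a6 was highest (50.1 CPM). Neighbouring cells and a change within the captured neurons therefore cannot be told apart.

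Of 100 splits of the 9 libraries into 4 and 5, the real one included, 4 called at least 1 gene. Such a count was uncommon, but it says little about chance, since Asl, called in the real split, is the target of the knockout. No other split drawn called Asl. For other genes chance cannot be excluded. Of the 100 splits, 83 had at least the 299 genes of the real one at an unadjusted edgeR p under 0.05. For gene lists, 69 of 100 splits gave at least 1, so chance cannot be excluded for the 1 list of the real split. The highest number among the other splits was 11 for genes and, in different splits, 10 for lists.

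The split with 11 genes separated the 5 libraries above 10000000 counts (lowest 10975265) from the 4 below (highest 9524730). This split may mark a structure of the samples that cuts across genotype. It was examined because it had the most calls, so its counts are compared with the others after selection. It gave 1724 genes at an unadjusted p under 0.05, against 299 for genotype and a median of 432 over the other splits. After thinning all libraries to 8958530 counts there were 1705, of which 1652 were among the 1724 and differed in the same direction. Thinning keeps each gene's expected share of the counts, so a similar result was to be anticipated. Unequal sampling depth does not account for the difference, but preparation differences that go with depth were not tested. Transcript length correlated with the fold change of larger over smaller libraries across 11954 genes (Spearman −0.219). Genes are not independent replicates. From mean log2 CPM, 3 of all 126 splits, this one included, gave a correlation as large in size. A length-dependent difference in library preparation is therefore a candidate explanation. GC content gave −0.069, which argues against GC bias between these classes only. With the fold change of cKO over WT, GC content gave −0.130 and length −0.024. Mdh1 (log2 fold change 0.72) and App (−0.64), named after their values were seen, were among the 11 genes; with the class as a term Asl was still called (−2.50, adjusted p = 0.0178).

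Single libraries differed in other ways. WT 1 had the lowest median correlation with the others (0.853) and 67 genes that were absent there but well counted elsewhere, against at most 30 in any other library. Purkinje cell genes were high in WT 3 (Pcp2 92.0, Calb1 229 and Car8 221 CPM), cKO 2 (127, 240 and 218 CPM) and cKO 4 (46.8, 69.3 and 61.8 CPM), and Pcp2 was below 1 CPM in the other 6.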
